A study of Mus musculus with 8 samples.

How the data were processed

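RNA sequencing of liver was done on 8 mice, 4 Sost-/- and 4 SostPB/-, all on the MCD diet. Per the labels' protocols, RNA was extracted with RNAiso Plus, poly-A RNA was captured with a TIANSeq kit, and libraries were made with a TIANSeq fast library kit. The submitters' processing notes name HISAT2, StringTie, DESeq2 and the build mm10, with no version. The annotation release, the strand setting and the read length are not given in the sources used here. Groups and replicate numbers were taken from the sample titles, and each column from the sample description that carries its name.

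The authors deposited a table of whole-number counts with 55416 rows, each named by a versioned Ensembl gene ID and a symbol. No row was without a gene, and 1597 symbols repeated an earlier row. The authors also deposited a second table of 22883 rows with a normalized signal per gene, named by symbol alone. Each of its columns equalled the counts divided by 1 size factor. After multiplication by that factor, 100% of values were whole within 0.001. Its factors ran from 0.782 to 1.24, and it held rows with a total of at least 2 counts. All tests used the counts. The reads recovered from the second table were tested as an added alternative.

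The row names were checked against GENCODE M21, the GRCm38 annotation at hand. Of the rows, 52083 had an ID in it when versions were ignored, and positions were taken by ID. In 52046 of these the version was above that of M21, in 48081 of them by exactly 1, and in 2 it was below. The version was equal in 35 rows, and all 35 were on the mitochondrial genome, which has 37 rows. Because abundant liver genes were missing from their rows, 738 genes of families used in all cells were picked by symbol pattern, and runs of such genes with a mean of 100 counts or more were scored along each chromosome (assumed detected share of 0.95 where names hold and 0.15 elsewhere, minimum score 5). For each candidate run, and for 512 windows of 200 rows, exons were moved in steps of 50 bp up to 1.5 Mb each way. At each step log2 of the mean count plus 1 was correlated with the overlap of the row's exons with coding exons. A run was kept when its best shift lay within 1 kb. Of 5 runs, 3 were kept, with 1433 rows of which 562 are protein coding. The runs on chromosomes 11 and 19 were dropped, at best shifts of -109200 and -22700 bp. No coordinate was converted between builds. In simulated windows the scan found 4 of 4 known shifts within 500 bp. Those counts were drawn from the same exon overlap that the scan measures, with a constant shift in each window. They check the script and do not show how accurate the scan is on the real windows.

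Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM scaling, estimated dispersions, glmQLFit and glmQLFTest for SostPB/- over Sost-/-, and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was taken as its size over the square root of F. The common dispersion was 0.174 over all rows, and the median dispersion per row was 0.124 over all rows and 0.0624 over name-holding rows. CPM values use TMM-scaled totals of the tested rows. DESeq2 1.42.0, limma 3.58.1 with voom and sample quality weights, RLE and plain library totals, other filters, replicate number as a block and leaving out each library were alternatives. Gene lists were tested with camera. The design, the alternatives, the lists and the rule for named genes were fixed before the data were examined. The shift scan, the restriction to name-holding rows, DESeq2 on edgeR's rows and the test with unadjusted p around Sost were chosen after seeing the data.

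The rule named Sost and its receptors, 12 genes of fibrosis, inflammation, lipid handling and Wnt signalling, up to 4 genes per list described, and the 10 largest rises and falls among genes that passed, or the 10 smallest p values if fewer than 10 passed. Since rows outside the name-holding stretches were not shown to count the gene they name, the rule for the 10 smallest p values was also applied to nuclear name-holding rows with a mean of at least 50 counts, leaving out predicted genes and pseudogenes. List members in name-holding rows were named, apart from an item that is not reported here.

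Scripts were tested on simulated counts drawn from the real means, dispersions and library sizes. Over all rows, with 9550 tested and 181 of them changed, 13.2% of 2-fold and 65.6% of 4-fold changes were recovered, with 4 calls on unchanged rows. DESeq2, with 10020 tested, recovered 70.7% of 4-fold changes, with 30 calls on unchanged rows. In the 485 simulated name-holding rows 55% of 2-fold and 100% of 4-fold changes were recovered, with 2 calls on unchanged rows. For the lists, a rise of 0.5 in the mitochondrial list was found among 37 lists with 0 other lists called. Rows were drawn independently of each other there, while in the data the estimated correlation within this list was 0.842. The simulation therefore does not test calls of a list whose members vary together. Every pair of libraries differed by more than sampling noise (lowest chi-square per degree of freedom 41.3), so each was counted as 1 replicate. The list of sex chromosome genes was kept as a sample check and was not used, since its rows lie outside the name-holding stretches. Lists for neutrophils, acute phase, erythroid cells, exocrine pancreas and adipocytes had under 3 rows and were not tested. Counting intervals and limits cover counting error only.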

Results

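Poly-A RNA from the livers of 8 mice on the MCD diet was sequenced, 1 library per mouse. MCD stands, in its usual sense in this field, for a diet lacking methionine and choline, which is used to bring on steatohepatitis. The mice formed 2 genotype groups of 4, Sost-/- and SostPB/-, numbered as biological replicates. Sost encodes sclerostin, a secreted inhibitor of Wnt signalling, and the series asks how its overexpression affects steatohepatitis in mice. The labels do not say what PB stands for, and the series text does not say which group overexpresses Sost, so the groups are compared here by name. The libraries held 14932773, 10554376, 10416392 and 9919069 counts in Sost-/- replicates 1 to 4, and 9578086, 14613316, 10412498 and 10296297 in SostPB/- replicates 1 to 4. Total counts did not differ by more than the spread between replicates (exact two-sided permutation test, p = 0.657, n = 4 per group), and 0.0286 is the smallest p that 4 against 4 libraries can give.

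What each row of the table counts had to be settled first. Genes that a liver expresses at very high levels were nearly empty in their own rows. Over the 8 libraries the row named Alb (albumin) had a mean of 43.8 counts, Apoa1 (apolipoprotein A-I) had 4.25, and Ttr (transthyretin), Ahsg (fetuin-A), Apob and Cyp2e1 had 0. The largest nuclear rows carried names of genes that are not abundant in liver, such as Col19a1 with a mean of 132525 counts, Galr2 with 82409 and Dsg3, a skin desmosome protein, with 80966. Among 738 genes of families that all cells use (ribosome, proteasome, respiratory chain, translation, splicing), 161 or 21.8% reached a mean of 100 counts. A search along the GRCm38 assembly for runs of such genes, with the scan below, left 3 stretches, on chromosome 4 (3831334 to 62426990), chromosome 6 (3498382 to 30896794) and chromosome 15 (8109273 to 35938246). Inside these, 24 of 25 such genes reached 100 counts and outside them 137 of 713 did, a contrast that restates how the stretches were found. Of the other protein-coding genes, which were not used to find the runs, 289 of 537 (53.8%) reached 100 counts inside and 3117 of 20589 (15.1%) outside. On chromosome 4 no gene of the ubiquitous families lies between Mrpl50 (from 49512596) and Prpf4 (from 62408797). Prpf4, at the end of the stretch, had a mean of 103.6 counts, just above the limit. Names are therefore thinly anchored in that part, where Smc2, Klf4, Mup7 and Zfp37 lie.

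**Figure D1:**
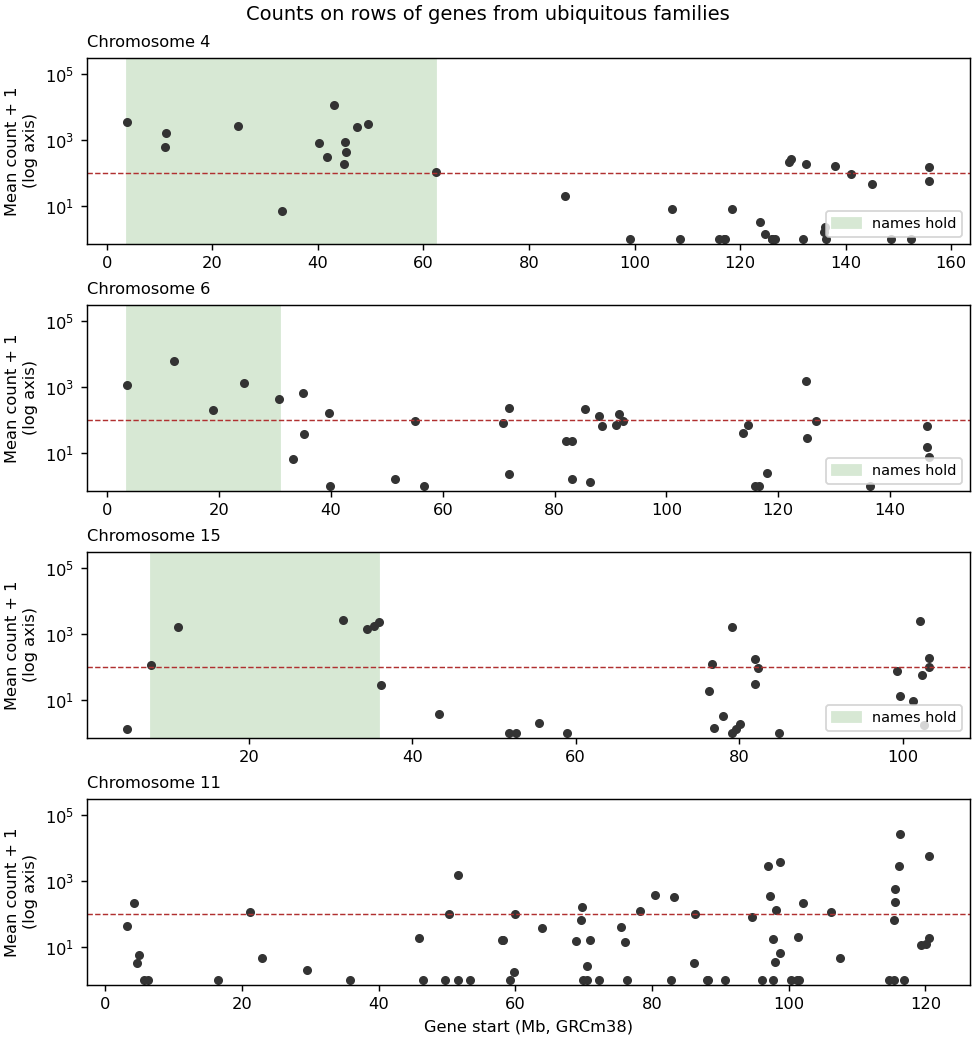
Each point is a gene of a ubiquitous family, placed by its start (Mb, GRCm38) and by the mean count of its row over the 8 libraries plus 1 (log axis), on chromosomes 4, 6, 15 and 11. The dashed line marks 100 counts above that offset and the shading the 3 stretches found as runs of points above it, with 24 of 25 points above the line inside them.

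A scan along the genome looked for the same mismatch as a distance. For 200 rows at a time, the exons of each row were moved by up to 1.5 Mb, and the log count was correlated with the overlap of the moved exons with protein-coding exons. In 496 of 512 windows the best correlation lay more than 1 kb from the annotated position, with a median distance of 148 kb. Of 470 pairs of neighbouring windows that share no row, 24.5% agreed on their best distance within 2 kb, against at most 3.19% in 1000 permutations of the windows. Most pairs did not agree, so the best distance of a single window and the median distance are uncertain. The best distance was within 1 kb in 16 windows, among them the first windows of chromosomes 2 and 9, which lie outside the 3 stretches. On the 3 stretches named above the best shift was 150, 150 and 100 bp. The rows on these stretches, 1433 of 55416 in the table, and the 37 mitochondrial rows are called name-holding from here on. Values of single genes are given for them, and any other row is spoken of by its name only.

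**Figure D2:**
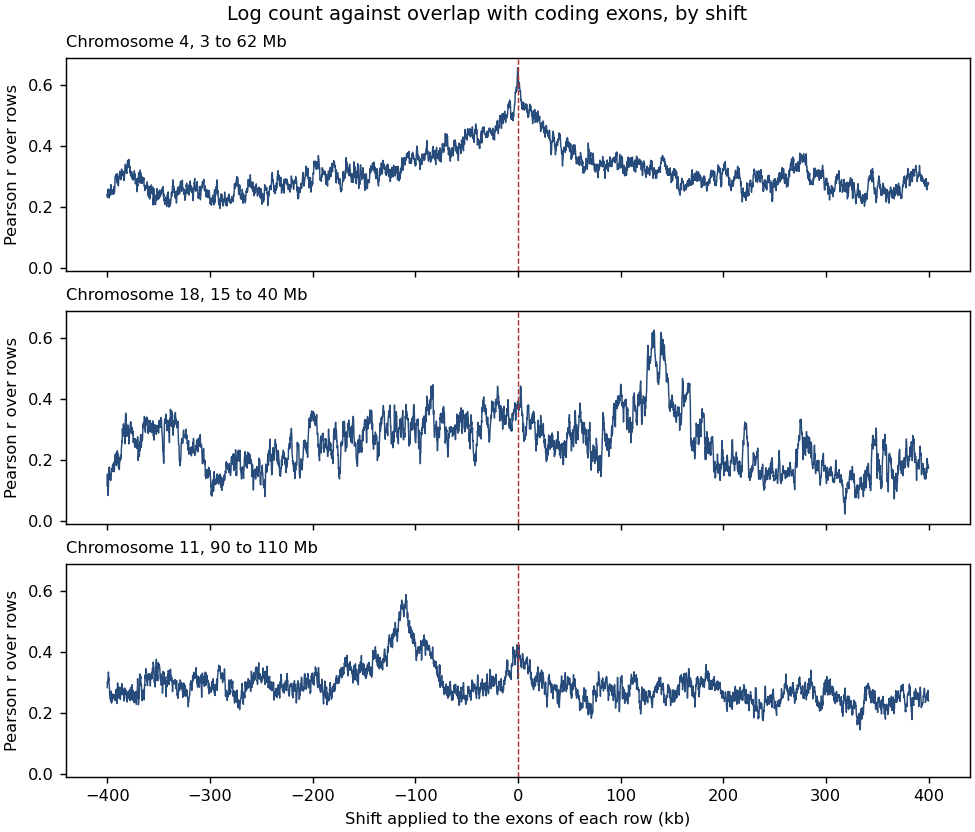
Pearson correlation, over the rows of a region, of log count with the overlap between the row's exons and protein-coding exons (vertical axis), when the exons are moved by the distance on the horizontal axis (kb). The curve for chromosome 4 peaks at the dashed line of no shift, while those for chromosomes 18 and 11 peak away from it.

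The row named Sost held 0 counts in all 8 libraries. It lies on chromosome 11 (101962458 to 101967015, GRCm38), outside the stretches where names were found to hold, so this value cannot be taken as the level of Sost RNA in either genotype, and the level of the gene altered in these mice is not analysed here. A count of 0 allows up to 3 counts per library in that row. The rows of its receptors Lrp4, Lrp5 and Lrp6 lie outside as well and had means of 9.38, 288 and 600.5 counts.

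The comparison of SostPB/- with Sost-/- livers asks which transcripts differ between the genotypes. Among the genes whose rows could be read by name, none passed edgeR's test, and those with the smallest p values follow. Adjusted p values of single genes, here and below, are over all rows tested in the fit unless stated. Slc25a51, which carries NAD into mitochondria (ENSMUSG00000045973, chromosome 4, 45395923 to 45408766), had 600.4 ± 145 CPM (counts scaled to a common library size) in Sost-/- and 317 ± 83.3 CPM in SostPB/- (SD, n = 4), with no overlap between the groups. Its log2 fold change was -0.92 with a standard error of 0.23, and edgeR's adjusted p was 0.540, or 0.251 over name-holding rows alone. C9orf72, a regulator of membrane traffic (chromosome 4, 35191285 to 35226175), had 309 ± 109 CPM against 143 ± 47.0 CPM (SD, n = 4; log2 fold change -1.11, SE 0.29). Its edgeR adjusted p was 0.544, or 0.251 over name-holding rows alone. Retreg1, a receptor for the turnover of endoplasmic reticulum (chromosome 15, 25843180 to 25973687), had 468 ± 53.2 against 340.1 ± 19.2 CPM without overlap, at a log2 fold change of -0.46 (SE 0.14). Aass, an enzyme of lysine breakdown (chromosome 6, 23072173 to 23132986), had 1204 ± 151 against 914 ± 47.4 CPM without overlap, at -0.40 (SE 0.14). Trp53inp1, a stress protein induced by p53, had 1085 ± 429 against 577 ± 270.3 CPM, at -0.91 (SE 0.35). Sema5a had a log2 fold change of -1.08 (SE 0.32), Impdh1, of guanine nucleotide synthesis, -0.57 (SE 0.22), and the zinc finger gene Zfp37 -4.11 (SE 1.54). Zfp37 varied widely, with 257 ± 273 CPM in Sost-/- and 15.02 ± 18.3 CPM in SostPB/- (SD, n = 4) and overlapping groups, and its log2 fold change was -5.09 without SostPB/- replicate 3 and -3.37 without Sost-/- replicate 1. Zfp37 also lies in the thinly anchored part of the chromosome 4 stretch, so its name is less certain. Smc2, a condensin subunit, was at 0.79 (SE 0.26) and Lsm8, which binds U6 RNA, at 0.56 (SE 0.21). These 10 were the nuclear name-holding genes with the smallest p, from 0.00249 to 0.0265 before adjustment in edgeR's quasi-likelihood test.

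Of 494 name-holding rows tested, 0 passed an adjusted p of 0.05 and 46 (9.31%) had an unadjusted p under 0.05 in edgeR's test, adjusted over these rows alone. DESeq2 called 5 of them: Slc25a51, C9orf72 and the predicted gene Gm11827 lower, the pseudogene Gm11914 and the transfer RNA row mt-Tw higher in SostPB/-. Limma-voom with sample weights called 0. In 20 of these rows (4.05%) the groups did not overlap, where chance gives 2.86%. Mitochondrial counts, 51.9% of the total in Sost-/- and 59.3% in SostPB/-, entered the library sizes behind these values, and with nuclear rows alone edgeR also called 0.

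Of the liver list genes on the name-holding stretches, those given here did not pass the test, and the rows of Mup1 and Mup20 were nearly empty, with means of 1.25 and 0 counts. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 606 ± 268 CPM in Sost-/- and 674 ± 378 CPM in SostPB/- (SD, n = 4; log2 fold change 0.15, SE 0.41). Baat, which conjugates bile acids, had 452 ± 82.2 and 440.5 ± 54.5 CPM (log2 fold change -0.04, SE 0.17). Decr1, of fatty acid oxidation, had a log2 fold change of 0.02 (SE 0.14) and the mitochondrial aldehyde dehydrogenase Aldh1b1 of 0.01 (SE 0.18). Pdk4, a kinase that holds back pyruvate oxidation and rises in fasting, varied widely between mice, with 2515 ± 1709 CPM in Sost-/- and 952 ± 908 CPM in SostPB/- (SD, n = 4). Its log2 fold change of -1.40 (SE 0.65) had an edgeR adjusted p of 0.785, or 0.533 over name-holding rows alone. Without SostPB/- replicate 2 the log2 fold change was -2.32 (SE 0.56, edgeR adjusted p = 0.432). Mup7, of the major urinary proteins, had 1143 ± 356 and 999 ± 1124 CPM (SD, n = 4), a log2 fold change of -0.19 (SE 0.67) that was -1.32 (SE 0.50, edgeR adjusted p = 0.968) without SostPB/- replicate 4. Its family has near-identical members, so its reads cannot be told apart from theirs. With the rows of Mup1 and Mup20 nearly empty, the name of Mup7, in the thinly anchored part of chromosome 4, is less certain.

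The fibrosis genes that could be read did not differ beyond the spread. Col1a2, a chain of type I collagen (chromosome 6, 4504814 to 4541544), had 108 ± 33.4 CPM in Sost-/- and 127 ± 25.6 CPM in SostPB/- (SD, n = 4; log2 fold change 0.23, SE 0.23). Col15a1 had -0.01 (SE 0.27) and the TGF-beta receptor Tgfbr1 -0.15 (SE 0.14). Of the Wnt lists, the ligand Wnt2 had 8.95 ± 2.79 and 4.08 ± 3.11 CPM, a log2 fold change of -1.13 with SE 0.74 (edgeR adjusted p = 0.924). The asparagine synthetase gene Asns, a target of the integrated stress response, stood at -0.92 (SE 0.39), and the viral RNA sensor Ddx58 at 0.19 (SE 0.17). The nuclear respiratory chain genes Ndufa4 and Cox6c had -0.22 (SE 0.21) and -0.10 (SE 0.19), and the ribosomal protein gene Rpl30 had 0.62 (SE 0.27). Klf4, Aqp7 and the B cell gene Pax5, at under 10 CPM in both groups, had -0.06 (SE 0.52), 0.06 (SE 0.37) and 0.26 (SE 0.65), and Klf4 was at -0.97 (SE 0.33) without SostPB/- replicate 2. Each of these genes had an edgeR adjusted p above 0.05.

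**Figure D3:**
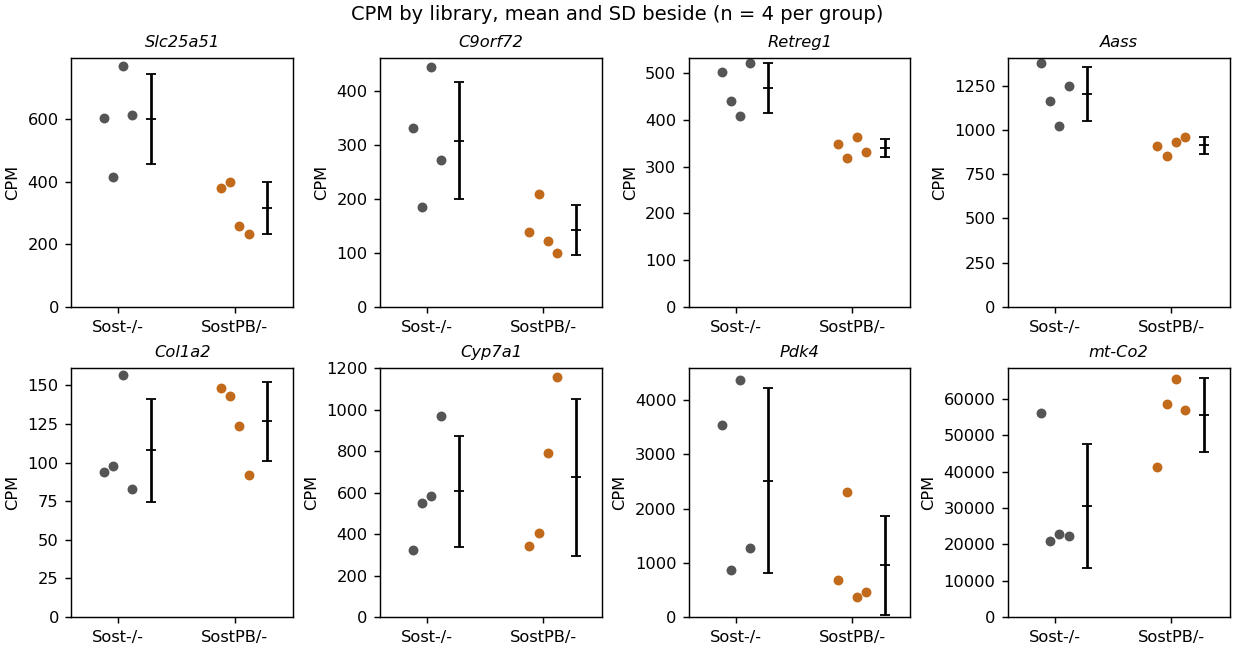
CPM values (vertical axes, linear from 0) of 8 name-holding genes in each of the 4 Sost-/- and 4 SostPB/- livers, with the group mean and SD beside the points. Slc25a51, Retreg1 and Aass show no overlap between the groups, and 1 Sost-/- library stands apart in mt-Co2 at 56062 CPM.

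Mitochondrially encoded transcripts made up 51.9% ± 5.14 of counts in Sost-/- and 59.3% ± 3.92 in SostPB/- livers (SD, n = 4; exact two-sided permutation test, p = 0.114). Both shares are of counts that fell on rows. Of all counts, mitochondrial ribosomal RNA held 2.55% ± 0.516 in Sost-/- and 2.10% ± 0.413 in SostPB/- (exact permutation test, p = 0.229), and mt-Co1 17.6% ± 0.425 and 17.5% ± 0.668 (p = 0.943; SD, n = 4 in each). All 13 protein-coding members of the list had a positive log2 fold change, with a median of 0.42, but 0 of 13 passed in edgeR, also when adjusted over the list alone, and 6 had an unadjusted p under 0.05. With library totals alone as the scaling the median was 0.23 and 12 were positive. mt-Co2, a subunit of cytochrome oxidase, had 30494 ± 17066 and 55642 ± 10256 CPM (log2 fold change 0.87, SE 0.31). Its edgeR adjusted p was 0.693, or 0.526 over name-holding rows alone. Without Sost-/- replicate 1, whose mt-Co2 value of 56062 CPM was among those of SostPB/-, the log2 fold change was 1.34 and edgeR's adjusted p 0.0317. mt-Nd2 had 0.56 (SE 0.22), mt-Nd1 0.52 (SE 0.21) and mt-Co1, the most abundant, 0.18 (SE 0.14); mt-Co1 was at -0.01 with totals alone. The counting strand is not given in the sources used here, so the pairs that overlap, mt-Atp8 with mt-Atp6, mt-Nd4l with mt-Nd4, and mt-Nd6 with mt-Nd5, cannot be fully separated.

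Of 43 gene lists written for liver, fibrosis, immune cells, Wnt signalling and diet, 38 had at least 3 rows in the test. Camera with a preset correlation of 0.01 called 1, the mitochondrially encoded list, higher in SostPB/- (adjusted p = 3.94e-07). With an estimated correlation, which was 0.842 within this list, its adjusted p = 0.736 and 0 lists were called, and 0 were called by exact permutation of the mean list score either (adjusted p = 0.362 for this list). It was the list with 13 of 13 members in name-holding rows, and none of the others had 3 tested there. The other 37 lists were therefore tested mostly on rows outside the name-holding stretches, and their results describe rows. Next in order came NRF2 and glutathione, upward with 7 rows (adjusted p = 0.138), and the neighbours of Sost, downward with 13 rows (adjusted p = 0.143, both by camera).

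Over all rows, 10020 were tested, 0 passed an adjusted p of 0.05 in edgeR, and 646 (6.45%) had an unadjusted p under 0.05. DESeq2, which gave an adjusted p to 12666 rows, called 53, of which 12 were higher and 41 lower in SostPB/-, and 48 of the 53 were among edgeR's rows. Run on edgeR's rows alone it called 59, and limma-voom with sample weights called 1. In simulated counts of the same design, with 181 changed rows among those edgeR tested, DESeq2 made 30 calls on unchanged rows and edgeR 4. These numbers depend on the changes planted, so they give no share of false calls among the 53. The 10 rows with the smallest p carried the names Odad4, Sstr3, Rcbtb1, Srr, Six3os1, Morn3, Taf2, Il1r1, Gm6416 and Gm11914; none passed, and the first 9 lie outside the name-holding stretches. The row named Odad4 had 6.35 ± 2.32 CPM in Sost-/- and 31.7 ± 5.71 CPM in SostPB/- (SD, n = 4; log2 fold change 2.32, SE 0.28, edgeR adjusted p = 0.0723). The row named Morn3 had a log2 fold change of -0.97 (SE 0.18) and that named Il1r1 -1.52 (SE 0.28). The rows named Sstr3 and Srr held 0 counts in all 4 SostPB/- libraries, with 2.02 ± 0.273 and 1.92 ± 0.452 CPM in Sost-/-, and the row named Gm6416 held 0 in all 4 Sost-/- libraries, with 1.59 ± 0.464 CPM in SostPB/-.

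The genes fixed beforehand for fibrosis, inflammation, lipid and Wnt readouts could not be read. The rows named Col1a1, Timp1, Adgre1, Tnf, Ccl2, Axin2 and Glul held 0 counts in all 8 libraries. Those named Acta2, Cd36, Tgfb1, Cpt1a and Fasn had means of 4.13, 7.25, 255, 542.5 and 966 counts. All 12 lie outside the name-holding stretches, and no fold change is given for them.

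Rows around Sost were compared with the rest of the genome, since the altered allele could carry linked differences. With 0 rows called the planned test was void, and rows with an unadjusted p under 0.05 were used instead. Within 10 Mb of Sost 14 of 201 rows (6.97%) had such a p, against 632 of 9819 (6.44%) elsewhere (Fisher's exact test, two-sided, p = 0.771). The window was far wider than the median best distance of 148 kb in the scan, although that median is uncertain.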

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

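The comparison of each library with its own group, by the gap to the nearest library over the group's range, was run on 92 sets of 4 values, and 7 stood out where chance gives about 1 in 20. The tests of the patterns below were chosen after the results were seen, except those on rows above 0.

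By total counts, Sost-/- replicate 1 with 14932773 and SostPB/- replicate 2 with 14613316 lay above the rest of their groups, which reached 10554376 and 10412498. In the number of rows above 0, SostPB/- replicate 4 was low, at 14459 against 14735 to 14762 in its group. Sost-/- replicate 1 was high in mt-Co2, at 56062 CPM against 20822 to 22783, and in mt-Co3, at 29537 CPM against 20078 to 20884. SostPB/- replicate 2 was high in Pdk4, at 2300 CPM against 367 to 679.9, and in Klf4, at 19.9 CPM against 3.51 to 5.09.

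The first pattern was that row names and counts did not belong together over most of the genome; low depth or degraded RNA is argued against as the whole cause, since 51.0% of protein-coding genes that were not used to find the 5 runs reached 100 counts in them, against 15.02% elsewhere and at most 27.8% in 1000 draws of random stretches. Another tissue stays open: 7 of 9 liver list genes on the name-holding stretches, or 77.8%, were at 1000 counts or more, under the bound of 80% set for excluding it, with Mup1 at 1.25 and Mup20 at 0. An annotation made for another genome build than the alignment is a candidate explanation: of 470 pairs of neighbouring windows that share no row, 24.5% agreed on their shift within 2 kb, against at most 3.19% in 1000 permutations. ID versions above those of the GRCm38 annotation go with it. At the estimated shift 10 of 18 abundant hepatocyte genes had a row with 1000 counts or more, against 1 at their own row and 1 at the opposite shift. The shifts were fitted to these same counts and the opposite shift was not, so this is not independent support. Cps1 was counted each time by its own row. No biological explanation was tested.

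The second pattern was that the list of 13 mitochondrially encoded protein-coding transcripts was higher in SostPB/-, while the share of mitochondrial ribosomal RNA was lower (2.10% against 2.55%) and that of mt-Co1 was 17.5% against 17.6%. Chance could not be excluded, since 4 of 35 splits of the libraries gave a list p as small, with the real -log10 p at 7.02 and the highest of the others at 12.9. That highest split set Sost-/- replicate 1 with SostPB/- replicates 2 to 4 and also had 970 rows with an unadjusted p under 0.05 against 646 in the real one. Exchanged labels of Sost-/- replicate 1 and SostPB/- replicate 1 stay open, with 2 of 6 values nearer to the other group. Both were chi-square per degree of freedom (61.5 against 116 to the own group, and 66.6 against 67.8). That distance took in the mitochondrial rows, so it is not independent of the pattern. Rows above 0, at 16222 and 14735, lay within the libraries' own groups. So did the first principal component of name-holding rows, at -6.88 and 9.77. These values go against an exchange. Nuclear counts that miss their rows stay open too, since the list median lay 0.43 above that of nuclear name-holding rows, but this contrast was within the spread of the mice (exact permutation test of the mean score, p = 0.0857), as does an effect of genotype or of RNA composition.

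The third pattern was that more rows held counts in Sost-/- (16073 ± 497) than in SostPB/- (14678 ± 146; SD, n = 4), with no overlap (exact two-sided permutation test, p = 0.0286, the smallest that 4 against 4 can give). Depth is argued against: after thinning all libraries to 3716995 nuclear counts, Sost-/- libraries still had 15041 to 16180 rows and SostPB/- libraries 14276 to 14718, a difference of -1151 rows. Reads spread over the genome from DNA or unspliced RNA stay open. They were predicted to raise the share of nuclear name-holding counts outside protein-coding rows in Sost-/-. That share was instead higher in SostPB/- by 0.178 percentage points, at 2.62% against 2.44%. This cannot decide, since the number of name-holding rows with counts did not separate the thinned groups, as given below. All nuclear rows with a mean under 10 held 0.619% of nuclear counts in Sost-/- and 0.607% in SostPB/- (exact permutation test, p = 0.8). On name-holding rows alone the thinned groups overlapped, at 586.5 ± 19.7 against 564 ± 6.28 rows (SD, n = 4; exact permutation test, p = 0.0857). Genotype and unrecorded preparation batches stay open.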

How the results depend on the processing

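The alternatives were planned before the data were examined, apart from those on nuclear rows, on name-holding rows, on recovered reads, with DESeq2 on edgeR's rows and around Sost. Over all rows edgeR's count of 0 became 53 with DESeq2 on its own choice of rows and 59 with DESeq2 on the rows edgeR tested, 2 with no filter beyond a count above 0 and 1 with limma-voom. It stayed 0 with RLE, library totals, the stricter filter, nuclear rows alone and recovered reads. Under the 2-fold limit 0 was fixed in advance, since no row was called without it. Without single libraries it ran from 0 to 4: 4 without Sost-/- replicate 1, 2 without Sost-/- replicate 4, 1 each without Sost-/- replicates 2 and 3 and SostPB/- replicates 3 and 4, and 0 otherwise. On name-holding rows the count of 0 became 5 with DESeq2, 6 with DESeq2 on edgeR's rows, and ran from 0 to 2 without single libraries. It was 2 (mt-Tw and mt-Co2) without Sost-/- replicate 1, and 1 without SostPB/- replicate 3 (Nipbl) or 4 (Mup6). The cause was not tested. With the replicate block edgeR called 0 over all rows and 0 name-holding rows, and rows with an unadjusted p under 0.05 went from 646 to 473. The numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.04, -0.01, -0.03 and 0.04, and 1 of 4 Sost-/- libraries correlated best with its own number. The block changed no other call.

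The single list called became 0 with an estimated correlation, 0 by exact permutation, and 0 on nuclear rows alone, where the list is absent by construction. It was 1 with RLE, totals, the block and without any single library. The median of the mitochondrial list ran from 0.27 without SostPB/- replicate 3 to 0.63 without Sost-/- replicate 1. Of 33 single rows under 396 alternative fits, 380 kept direction and side, 15 gained a call (12 by DESeq2) and 1 reversed, mt-Co1 at -0.0097 with library totals. Around Sost, the share of rows with an unadjusted p under 0.05 was 9.23% in a 2 Mb window, and over the whole chromosome it reversed to 6.12% against 6.48% elsewhere. The planned tests of the Sost level and of called rows around Sost gave no value, since the row was at 0 and no row was called.

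Any split gives at least the 0 edgeR calls, so its 35 of 35 (highest other 2) says nothing about chance. Chance could not be excluded for the other counts: of 35 splits, 2 gave at least the 53 DESeq2 calls (highest other 101), 2 the 646 rows with an unadjusted p under 0.05 (highest other 970), 3 the 46 such name-holding rows (highest other 83), and 16 the 1 list called (highest other 2). Simulated data with these library sizes and dispersions recovered 13.2% of 2-fold changes over all rows and 55% on name-holding rows, so many changes of this size would be missed.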

Other observations

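The tests here were chosen after the results were seen. If the shifts are real, some rows of other names may carry the reads of abundant hepatocyte genes, a hypothesis that rests on the 24.5% agreement of neighbouring windows and was not checked with the reads. Under it the row named Kng1, with a mean of 114131 counts, would count Ahsg, and had a log2 fold change of -0.83 (SE 0.19) in SostPB/- over Sost-/-; edgeR's adjusted p was 0.461 and that of DESeq2 0.0202. The row named D030068K23Rik would count Tat, the tyrosine aminotransferase gene, at -1.33 (SE 0.37; adjusted p = 0.591 with edgeR and 0.0305 with DESeq2). The row named Gm43412 would count Hpd, the next enzyme of tyrosine breakdown, at -0.69 (SE 0.20, edgeR adjusted p = 0.591). The row named Dsg3 would count Ttr, at 0.35 (SE 0.15), Topbp1 would count Trf, at -0.08 (SE 0.15), and Ankrd45 would count Serpinc1, at -0.09 (SE 0.13), with no edgeR adjusted p under 0.05 among them. The other 4 rows of this kind were Gm39329 for Apoa1 at 0.19 (SE 0.26), Cep112 for Apoh at 0.15 (SE 0.15), Col27a1 for Ambp at 0.17 (SE 0.17) and Cps1 for Cps1 itself at -0.28 (SE 0.15), none with an edgeR adjusted p under 0.05. In simulated counts of this design, which held planted changes, DESeq2 made 30 calls on unchanged rows. That number depends on the changes planted, so it warns of false calls but does not give their share here.

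On the first principal component of the name-holding rows, which held 29.5% of the variance, the 4 Sost-/- libraries lay from -8.68 to -3.81 and the 4 SostPB/- libraries from 0.37 to 13.2. All libraries correlated better on these rows than over all tested rows: Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.950 to 0.978 against 0.876 to 0.921 within groups, and 0.939 to 0.973 against 0.878 to 0.907 between them.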
